A study of Homo sapiens with 21 samples.

How the data were processed

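RNA from LNCaP and abl prostate cancer cells was hybridized to Affymetrix human genome U133 Plus arrays, 21 arrays in 7 groups of 3. The groups were LNCaP with control siRNA, LNCaP with AR siRNA, abl with control siRNA, abl with AR siRNA (all 72 h after transfection), and abl with vehicle, abl with 100 nM DHT for 4 h and abl with 100 nM DHT for 16 h. Groups and replicate numbers were taken from the sample titles.

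The deposited values are probe set signal intensity on a linear scale, made with the Affymetrix GCOS software per the submitters' processing notes. Its algorithm settings and scaling target are not given in the sources used here. The table holds 54675 probe sets with intensities from 0 to 15751.2, of which 18 values are 0. The arrays were not on one scale: the log2 medians differed by 0.623, above the limit of 0.2 set before the data were examined, so the log2(signal + 16) values were quantile normalized between arrays. The 62 control probe sets were left out.

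Of the other 54613 probe sets, 41091 had 1 gene symbol in the platform table used here, 1801 had several and 11721 were not listed and stay unnamed. Symbols were updated by gene identifier. A probe set was kept if it lay above the array median on at least 3 of 21 arrays, which left 36836, of which 29399 had 1 symbol. A gene was represented by its kept probe set with the highest mean over the arrays, giving 15611 genes; 7512 of them had several kept probe sets. AR and NKX3-1 are among the genes with no probe set paired by that table, so their own levels, and with them the depth of the knockdown, are not reported here.

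Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with 1 mean per group and all 21 arrays in 1 fit, which leaves 14 residual degrees of freedom and a prior of 5.24. P-values were adjusted by Benjamini-Hochberg over the 15611 genes of each comparison, and a gene counted as changed at an adjusted p under 0.05. Adjusted p-values of genes come from this fit. Those of KLK3 probe sets that did not stand for the gene come from the same model fitted to every kept probe set with 1 symbol. The 7 comparisons were AR siRNA against control siRNA in each line, the difference between those changes, abl against LNCaP under control siRNA, DHT at 4 h and at 16 h against vehicle, and 16 h against 4 h. Overlaps of changed genes were tested with Fisher's exact test, which takes genes as independent. For the pair that shares the vehicle arrays, 50 simulations of unchanged groups were run with the spread estimated from all 21 arrays.

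The 21 gene lists were fixed before the data were examined: androgen-induced, androgen-repressed, mitosis, DNA replication, cholesterol synthesis, fatty acid synthesis, ER folding, amino acid stress, interferon response, NF-kB, p53 targets, immediate early, hypoxia and glycolysis, androgen metabolism, polyamine synthesis, AR cofactors, luminal, basal, neuroendocrine, stromal and mesenchymal, and leukocyte and endothelial genes. Some genes stand in more than 1 list. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 147 tests; 42 were called, and 10 with an estimated correlation. Those 10 were the androgen-induced list at 4 h and 16 h of DHT, fatty acid synthesis in abl against LNCaP and after AR siRNA in abl, and amino acid stress, ER folding and DNA replication at 16 h of DHT against vehicle and against 4 h. Counts adjusted over the list alone apply Benjamini-Hochberg within the list.

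The genes named were chosen by a rule set before the data were examined. Per comparison these were the 8 largest rises and the 8 largest falls among changed genes whose 3 arrays of one group all lay on one side of the other 3, with a group mean above the median of all tested genes, the markers KLK3, TMPRSS2, FKBP5, UBE2C, CDK1 and CDC20, and up to 4 members of each list described. Sex-linked marker genes and symbols of clones were left out. Genes outside this rule are named as such.

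The scripts were tested on simulated data with genes changed by known folds. In the comparison of AR siRNA with control siRNA in abl, 10.4% of 1.5-fold, 74.6% of 2-fold and 100% of 4-fold changes were recovered; at 4 h of DHT these shares were 20.9%, 73.1% and 98.5%, and for the difference between the knockdowns 2.99%, 35.8% and 97%. False calls numbered 5, 7 and 4, and with no changed gene 0 calls were made. The simulated noise was independent, with 1 spread per gene on all arrays, as the model assumes. These figures therefore do not cover arrays that vary together or unequal spread between the experiments.

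Alternatives set before the data were examined were the values as deposited, median centring, pseudocounts of 1 and 64, no filter, a filter on the mean, the mean of a gene's probe sets, specific probe sets where a gene has one, every probe set on its own, a fit of the compared groups alone, trended and robust eBayes, array weights, a replicate block, each array left out in turn, an adjusted p of 0.01, a 1.5-fold minimum, an estimated correlation in camera, and fry. Added after seeing the data were scaling to a common 2% trimmed mean, the 4 siRNA arrays numbered 1 left out or set as a block, and the ACTB 3'/5' ratio as a covariate. Specific here means only that the name of a probe set does not end in _x_at, _s_at or _a_at. Whether the other probe sets pick up further genes was not tested. No column of other samples was used.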

Results

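Gene expression was measured on 21 Affymetrix human genome arrays, with 1 RNA sample per array and 3 arrays in each of 7 groups. The cells were LNCaP, an androgen-responsive line from a metastasis of prostate cancer, and abl, a line derived from LNCaP by long culture without androgen. In the first experiment each line received a small interfering RNA (siRNA) against the androgen receptor (AR) or a control siRNA, and RNA was taken 72 h later. In the second experiment abl cells held in serum stripped of steroids received 100 nM dihydrotestosterone (DHT), the natural AR agonist, for 4 h or 16 h, or vehicle. The labels call the 3 arrays of a group biological replicates but do not say that they came from separate cultures. The spread between them may therefore be partly technical. In the main fit each limma p-value rests on 1 spread per gene, estimated from all 21 arrays of both experiments and not from the compared groups alone. The length of the vehicle treatment was not stated.

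The median signal of an array lay between 10.5 and 24.8. After normalization, the correlation across the 15611 tested genes between arrays of one group lay between 0.952 and 0.982. Genes are not independent replicates. The number of arrays limits the precision. The control probe sets of the 2 experiments differed: the ratio of the 3' to the 5' probe set of ACTB was 4.21 to 7.28 on the siRNA arrays and 1.74 to 1.98 on the DHT arrays, and the signal of the spiked BioC control was 691 to 1430.3 and 240.8 to 360.5. Levels are therefore compared within an experiment, except where the genes shared by the knockdowns are set against the vehicle arrays. All changes are on the log2(signal + 16) scale, which understates the change of dim genes and sets its size where a group lies near background. They are given with the standard error (SE) of limma's fit to all 21 arrays (n = 3 per group).

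The first comparison asked how the androgen-independent line differed from its parent under control siRNA. The transcriptome of abl was far from that of LNCaP: 3015 of 15611 genes differed, 1451 higher and 1564 lower in abl, and 883 of them differed at least 2-fold. In abl 49 of 57 mitosis genes, 8 of 14 fatty acid synthesis genes and 10 of 20 endoplasmic reticulum (ER) folding genes were higher, and 15 of 40 androgen-induced genes were lower. With an estimated correlation only the fatty acid list of these 4 kept its call (adjusted p = 0.141, 0.0201, 0.183 and 0.0649). OR51E2, an olfactory-type receptor of prostate cells, was 113-fold higher in abl (log2 6.82, SE 0.15, adjusted p = 7.38e-17). NETO1 was lower by the most, at log2 -6.04 (SE 0.25, adjusted p = 1.08e-12).

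Among the other genes highest in abl were WNT5A, a secreted Wnt ligand (log2 5.38, SE 0.14), FLRT3 (4.69), SLC7A5, an importer of large neutral amino acids (4.65), CHN1 (4.56), DOCK10 (4.52), AMOTL1 (4.46) and CCDC80 (4.29). Those lowest in abl included BCHE, which encodes butyrylcholinesterase (log2 -5.90, SE 0.18), LDHB, a lactate dehydrogenase subunit (-5.15), the thyroid hormone deiodinase DIO3 (-4.94), TMEM205 (-4.70), EFNB2 (-4.57), DSC2 (-4.50) and the neuropeptide precursor NTS (-4.36). Each of these genes stayed past the threshold when any 1 of the 6 arrays was left out.

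Of 57 measured genes of the mitosis list, 49 were higher in abl and 0 lower (51 and 0 when adjusted over the list alone), with a median of log2 1.27; the list's adjusted p was 2.41e-28 with the preset correlation and 0.141 with an estimated correlation. HMMR (log2 2.36, SE 0.25), KIF4A (1.82), SGO2 (1.79), BUB1 (1.78) and CDC20, an activator of the anaphase-promoting complex (1.75), were examples. The mitosis list was drawn up knowing that the study on these samples reported such genes, so its direction is not independent evidence. Of 51 DNA replication genes, 16 were higher and 0 lower (21 and 0 when adjusted over the list alone), among them RRM2 (1.41) and GINS1 (1.35); the adjusted p was 2.34e-06, and 0.353 with an estimated correlation.

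The fatty acid synthesis list kept its call with an estimated correlation (adjusted p = 0.0201; 4.05e-05 with the preset value). Of its 14 measured genes, 8 were higher in abl and 0 lower, also when adjusted over the list alone, with ELOVL6 at log2 1.64 (SE 0.19), FASN at 1.57, SCD at 1.48 and ME1 at 1.29. Of 20 ER folding genes, 10 were higher and 0 lower (12 and 0 when adjusted over the list alone), with DNAJB9 at 1.39 and PDIA6 at 1.11; the adjusted p was 2.34e-06, and 0.183 with an estimated correlation. The cholesterol synthesis list, with 6 of 19 genes higher and 2 lower (7 and 2 when adjusted over the list alone), had an adjusted p of 0.0254, and 0.348 with an estimated correlation. INSIG1 (1.55) and IDI1 (0.76) were higher and SC5D (-0.72) was lower; on specific probe sets IDI1 (0.64) and SC5D (-0.28) did not pass. Its list was not called without the second control array of LNCaP or the first of abl (median 0.20 and 0.21). The amino acid stress list, genes that cells switch on when amino acids run short, had 7 of 24 genes higher and 3 lower (10 and 3 when adjusted over the list alone; adjusted p = 0.0056, and 0.441 with an estimated correlation). Without the second control array of abl it was not called (median 0.18).

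Of 40 androgen-induced genes, 7 were higher in abl and 15 lower (7 and 19 when adjusted over the list alone; median log2 -0.23, adjusted p = 0.00953, and 0.0649 with an estimated correlation). ALDH1A3 (log2 -2.59, SE 0.30), PMEPA1 (-2.17), ABCC4 (-1.92) and ZBTB16 (-1.81) were lower, while TMPRSS2 differed by 0.08 (adjusted p = 0.793). KLK3, which encodes prostate-specific antigen, differed by log2 -0.67 on the probe set that stood for it (adjusted p = 0.0736). A second KLK3 probe set had signals of 162.5 to 421.1 on the LNCaP control arrays and of 2.6 to 3.4, below the array medians, on those of abl. It differed by log2 -3.86 (SE 0.215, adjusted p = 5.55e-11 over all probe sets). A further KLK3 probe set had signals of 136.9 to 391.3 in LNCaP and 1.5 to 15 in abl. It differed by log2 -3.43 (SE 0.337, adjusted p = 2.84e-07 over all probe sets). KLK3 was thus lower in abl on both of these. Their signals in abl lay near background, where the scale sets the size of a difference. The stromal and mesenchymal list had 0 of 15 genes higher and 5 lower, also when adjusted over the list alone (adjusted p = 0.0369, and 0.141 with an estimated correlation), with TWIST1 at -2.24 and VIM, the filament protein vimentin, at -1.24. The share of differing genes that were higher in abl was 48.1%, but 30.7% (937 against 2114) after median centring and 28.1% (277 against 708) on the values as deposited. The stromal list was not called without the first control array of LNCaP (median -0.04) or the second or the third of abl (-0.215 and -0.06).

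The next comparison asked which genes respond to AR knockdown in LNCaP. AR siRNA changed 499 genes, with 284 higher and 215 lower than under control siRNA; 77 changed at least 2-fold. UGT2B17, a glucuronosyltransferase that inactivates androgens, fell the most, 9.13-fold (log2 -3.19, SE 0.16, adjusted p = 5.14e-10), from 10.50 ± 0.09 to 7.31 ± 0.42 (SD, n = 3). Its neighbour in function UGT2B15 fell by log2 1.14 (SE 0.12), and of the androgen-induced genes SLC45A3 (prostein) fell by 1.15. On the probe sets that stood for the genes, APLP2, a relative of the amyloid precursor protein, rose the most (log2 2.06, SE 0.19, adjusted p = 6.43e-06). A further probe set of MLEC rose by 2.16.

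The other genes with the largest falls were DIO3 (log2 -2.77, SE 0.38), ANGPT2, an angiopoietin (-1.86), CCDC59 (-1.61), MAN1A1, a mannosidase of N-glycan trimming (-1.58), LYSMD4 (-1.54), the stress cytokine GDF15 (-1.39) and MYNN (-1.38). The largest rises after APLP2 were MLEC, an ER lectin (1.99, SE 0.20), TMCO1 (1.90), TMEM38B (1.80), STRADB (1.72), FYCO1 (1.58), TIMP2, a metalloproteinase inhibitor (1.54), and PCYOX1 (1.53). All of these except APLP2 stayed past the threshold without any 1 array. APLP2 has 8 kept probe sets, all higher, by log2 0.22 to 2.06, and 4 of them passed; leaving out an array of LNCaP with AR siRNA moved the choice to a probe set with a rise of 0.03 to 0.45. On specific probe sets, as set by their names, APLP2 (0.34), GDF15 (-0.90), UGT2B15 (-0.115) and ATF3 (-0.04) did not pass in LNCaP.

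Of 40 androgen-induced genes, 3 fell and 1 rose (6 and 3 when adjusted over the list alone), with a median of log2 -0.11; the adjusted p was 0.0154, and 0.0901 with an estimated correlation. SLC45A3 (-1.15), STK39 (-0.91) and C1orf116 (-0.51) fell and CREB3L4 rose (0.53). KLK3 was at -0.50 (adjusted p = 0.355), TMPRSS2 at -0.45 (adjusted p = 0.15) and FKBP5 at 0.00 to 2 decimals (adjusted p = 0.999). A second KLK3 probe set fell by 0.84 (SE 0.22, adjusted p = 0.0445 over all probe sets). Of 14 genes of androgen metabolism, 2 fell and 0 rose, UGT2B17 and UGT2B15 (also when adjusted over the list alone; adjusted p = 0.0143, and 0.113 with an estimated correlation). Both are also in the androgen-repressed list, genes that androgen lowers, so their fall runs against the direction that list names after loss of AR. Of its 11 genes 2 fell and 1 rose (2 and 3 when adjusted over the list alone), and the list was not called (median 0.26, mean -0.06, adjusted p = 0.869). The gene that rose was PLA2G2A, a secreted phospholipase (1.37, SE 0.33). PLA2G2A lost its call without the second or the third control array (1.21 and 1.20) or the first or second AR siRNA array (1.11 and 1.41). C1orf116 and CREB3L4 lost their calls without the second control array, among others (-0.59 and 0.46). The androgen-induced list was not called without the third control array (median -0.13) or the second AR siRNA array (-0.19). Its median was -0.17 without the first control array and -0.21 and -0.16 without the first or the third AR siRNA array.

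The mitosis list was lower after knockdown in LNCaP, with a median of log2 -0.39, but single genes mostly did not pass: 2 of 57 fell, NUF2 (-1.01) and CDCA8 (-0.96), and 0 rose (6 and 0 when adjusted over the list alone, which is not independent evidence). Its adjusted p was 2.16e-08, and 0.441 with an estimated correlation. UBE2C, CDK1 and CDC20 were at -0.39, -0.65 and -0.66, with adjusted p of 0.521, 0.217 and 0.0956. The amino acid stress list had 2 of 24 genes lower, the transcription factor ATF3 (-1.06, SE 0.18) and TRIB3 (-0.94), and 1 higher, VLDLR (0.53); 9 fell and 1 rose when adjusted over the list alone. Its adjusted p was 0.000251, and 0.314 with an estimated correlation. The interferon list (1 of 25 rose, IFITM1, and 0 fell, also when adjusted over the list alone; median 0.31) had an adjusted p of 0.00931, and 0.399 with an estimated correlation. It was not called without the first AR siRNA array (median 0.11) or the third control array (0.18), and was at 0.49 and 0.50 without the first control array or the third AR siRNA array. The immediate early list had 0 of 11 genes past the threshold (0 higher and 2 lower when adjusted over the list alone; adjusted p = 0.0242, and 0.183 with an estimated correlation) and was not called without the first or second control array (median -0.27 and -0.17) or the second or the third AR siRNA array (-0.15 and -0.27). Without the second control array NUF2 (-0.87), CDCA8 (-0.84), TRIB3 (-0.90), VLDLR (0.53) and IFITM1 (1.13) lost their calls.

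The count of 499 was 18 when the 6 arrays were fitted alone and 16 (11 higher, 5 lower, or 68.8% higher against 56.9%) on the values as deposited. It was 297, 166, 282 and 243 without the first or second control array or the second or the third AR siRNA array.

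In abl, AR siRNA changed 640 genes, with 359 higher and 281 lower; 95 changed at least 2-fold. Of the mitosis and amino acid stress genes, 15 of 57 and 7 of 24 fell (adjusted p = 0.183 for each list with an estimated correlation). CXCL8 (interleukin 8), CDKN1A (the cell cycle inhibitor p21) and GDF15 also fell, while 3 of 14 fatty acid synthesis genes and the acid phosphatase ACP3 rose. CXCL8 fell the most, from 6.54 ± 0.68 to 4.49 ± 0.28 (SD, n = 3), by log2 2.06 (SE 0.30, adjusted p = 0.000535). Under AR siRNA CXCL8 lay near background, where the scale sets the size of a fall, so its rank is not firm. APLP2 again rose the most (log2 2.44, SE 0.19, adjusted p = 1.37e-06); its 8 probe sets lay between 0.34 and 2.55, and without the first AR siRNA array the chosen one was at 0.41.

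The other leading rises were OR51E1, a second olfactory-type receptor (log2 2.01, SE 0.19), TMCO1 (1.99), the deiodinase DIO1 (1.86), MLEC (1.64), CD82, a tetraspanin (1.62), SURF4 (1.46) and STRADB (1.43). The other leading falls that held without any 1 array were CDKN1A (-1.57, SE 0.29), GDF15 (-1.52), ASNS, asparagine synthetase (-1.42), and ACYP1 (-1.42). S100P (-1.91), MTHFD2 (-1.35) and PBK, a mitotic kinase (-1.26), also fell, but lost their calls when some arrays were left out, for example at -1.45, -1.13 and -1.16 without the second control array for S100P and MTHFD2 and the third control array for PBK. On specific probe sets APLP2 (0.61), CD82 (0.35) and GDF15 (-0.81) did not pass in abl.

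Of the 57 mitosis genes, 15 fell after AR knockdown in abl and 0 rose (37 and 0 when adjusted over the list alone, which is not independent evidence), with a median of log2 -0.64; the adjusted p was 9.17e-22, and 0.183 with an estimated correlation. CDCA8, of the chromosomal passenger complex, fell by 1.22 (SE 0.25), CDC20 by 1.21 (adjusted p = 0.00236), NUF2 by 1.12 and CDK1 by 1.11 (adjusted p = 0.021). CDK1 and NUF2 lost their calls without the first or second AR siRNA array (-0.92 and -1.12, -0.85 and -1.11) or the second or the third control array (-1.13 and -1.01, -1.05 and -0.91). UBE2C was at -0.83 (adjusted p = 0.0792). Of 51 DNA replication genes 1 fell, DBF4 (-0.78), and 0 rose, also when adjusted over the list alone; the adjusted p was 0.0143, and 0.607 with an estimated correlation. DBF4 lost its call without the third control array, among others (-0.83). The list was not called without that array (median -0.20) or the first or second AR siRNA array (-0.12 and -0.17).

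Of 24 amino acid stress genes, 7 fell and 1 rose (13 and 2 when adjusted over the list alone), with a median of log2 -0.57; the adjusted p was 1.84e-06, and 0.183 with an estimated correlation. ASNS, MTHFD2, TRIB3 (-0.99, SE 0.20) and ATF3 (-0.82) were among them. ATF3 stood at 0.27 on its specific probe set. The fatty acid synthesis list kept its call with an estimated correlation (adjusted p = 0.046; 0.00109 with the preset value): 3 of 14 genes rose and 0 fell, also when adjusted over the list alone. These were the elongases ELOVL6 (1.15, SE 0.19) and ELOVL5 (0.61) and SCAP, an escort of sterol-sensing transcription factors (0.70). Of 19 cholesterol synthesis genes 1 rose, ACAT2 (0.67), and 0 fell (3 and 0 when adjusted over the list alone; adjusted p = 0.00924, and 0.264 with an estimated correlation). Of 20 ER folding genes 2 rose, SDF2L1 (0.74) and CREB3L2 (0.66), and 0 fell (4 and 1 when adjusted over the list alone; adjusted p = 0.0128, and 0.483 with an estimated correlation). MTHFD2 (-1.13), ATF3 (-0.70), ACAT2 (0.59) and SDF2L1 (0.63) lost their calls without the second control array and ELOVL5 (0.60) without the third. Without the third control array the cholesterol and ER folding lists were not called (median 0.07 and 0.18), nor was ER folding without the first control array (0.22) or the second AR siRNA array (0.20).

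The NF-kB list had 2 of 12 genes lower, CXCL8 and NFKBIA (-0.68), and 0 higher (4 and 0 when adjusted over the list alone; adjusted p = 0.0185, and 0.183 with an estimated correlation). Of 21 p53 targets, 3 fell, CDKN1A, GDF15 and ZMAT3 (-0.58), and 0 rose, also when adjusted over the list alone; the adjusted p was 0.0114, and 0.165 with an estimated correlation. The androgen-induced list was not called in abl (adjusted p = 0.87): 5 of 40 genes rose, with PLPP1 at 0.85, SPDEF at 0.70 and CREB3L4 at 0.68 as examples, and 1 fell, TRPM8 at -0.71 (8 and 7 when adjusted over the list alone). TMPRSS2 was at -0.35 (adjusted p = 0.249) and KLK3 at 0.33 (adjusted p = 0.537) on the probe set that stood for it. The second KLK3 probe set was at -0.06, with signals of 2.6 to 3.4 under control siRNA and 2 to 4 under AR siRNA. The third was at -0.05, with signals of 1.5 to 15 and 4.8 to 6.7. Such signals are too near background to show a fall of KLK3 in abl. ACP3, prostatic acid phosphatase, rose by 1.11 (SE 0.16) and the dopa decarboxylase gene DDC by 0.76. NFKBIA (-0.56), SPDEF (0.78) and TRPM8 (-0.67) lost their calls without the second control array and ZMAT3 (-0.53) without the third. The NF-kB list was not called without the second control array (median -0.10) or the first or the third AR siRNA array (-0.18 and -0.23).

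The count of 640 was 1 when the 6 arrays were fitted alone and 6 on the values as deposited (5 higher and 1 lower, or 83.3% higher against 56.1%). It was 297 with median centring, 376 and 349 without the second or the third control array, and 259 without the second AR siRNA array.

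**Figure D1:**
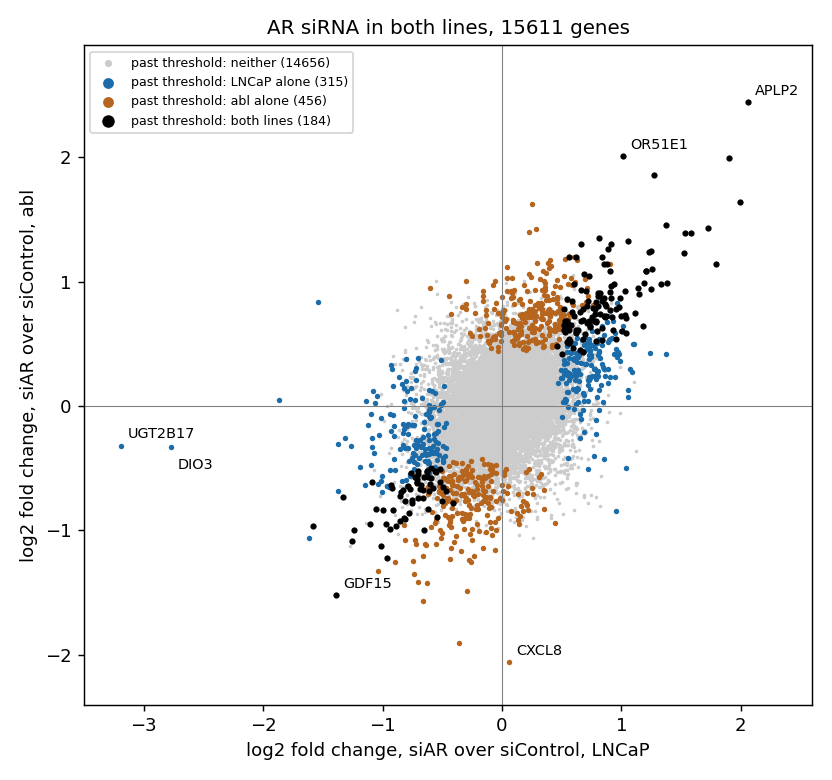
Each point is 1 of 15611 genes, placed by its log2 fold change under AR siRNA over control siRNA in LNCaP (horizontal) and in abl (vertical), 3 arrays per group. Black points (184 genes) passed the threshold in both lines, blue in LNCaP alone (315), brown in abl alone (456), and the rest (14656) in neither; no black point lies in a quadrant of opposite signs, and UGT2B17 lies far to the left with little change in abl.

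The 2 knockdowns were then compared with each other. The lines shared 184 changed genes, all in the same direction: 123 rose in both, against 6.53 for independent lists (Fisher's exact test, two-sided p = 2.27e-130, Benjamini-Hochberg 3.63e-129 over 16 overlaps), and 61 fell in both, against 3.87 (p = 1.25e-56, adjusted 1e-55). Shared genes included APLP2, MLEC, TMCO1 and STRADB, which rose, and GDF15, CDCA8, TRIB3 and ATF3, which fell. No gene changed in opposite directions, against 5.11 and 4.94 for independent lists (Fisher's exact test, p = 0.011 and 0.0107, adjusted 0.0251 for each). The correlation of the fold changes across genes was 0.368; genes are not independent replicates. The shared count depended on the fit: it was 3 on the values as deposited and 1 when the compared groups were fitted alone. It was 86 without the second control array of LNCaP and 108 without the third AR siRNA array of LNCaP. It was 118 without the third control array of abl and 114 without its second AR siRNA array.

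Whether the lines responded differently was tested directly. The difference between the knockdowns passed for 6 genes, 5 higher and 1 lower in abl than in LNCaP (limma's test of the interaction). An unadjusted p under 0.05 was found for 1262 of 15611 genes, where unchanged genes would give a share of 0.05 on average. UGT2B17 differed most, by log2 2.87 (SE 0.23, adjusted p = 1.64e-06): it fell 9.13-fold in LNCaP but went from 12.09 ± 0.03 to 11.77 ± 0.11 (SD, n = 3) in abl. LYSMD4 differed by 2.38 (adjusted p = 0.0127), ANGPT2 by 1.91 (0.00601), UGT2B15 by 1.17 (0.00542), PROS1, protein S, by 1.13 (0.0276), and GCLC, a subunit of the enzyme that starts glutathione synthesis, by -1.17 (0.0134). UGT2B15 and UGT2B17 are close paralogs whose probes can share signal, and UGT2B15 differed by 0.20 with specific probe sets, where its call was lost. The calls of LYSMD4, PROS1 and GCLC were lost without some arrays, among them the third AR siRNA array of abl (2.34, 1.08 and -1.16). With that array left out the interaction count was 3, as it was without the third control array of LNCaP, and it was 14 and 13 without the first AR siRNA array of LNCaP or of abl. On the values as deposited 2 genes passed and with median centring 3, all higher in abl (100%, against 83.3% here).

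**Figure D2:**
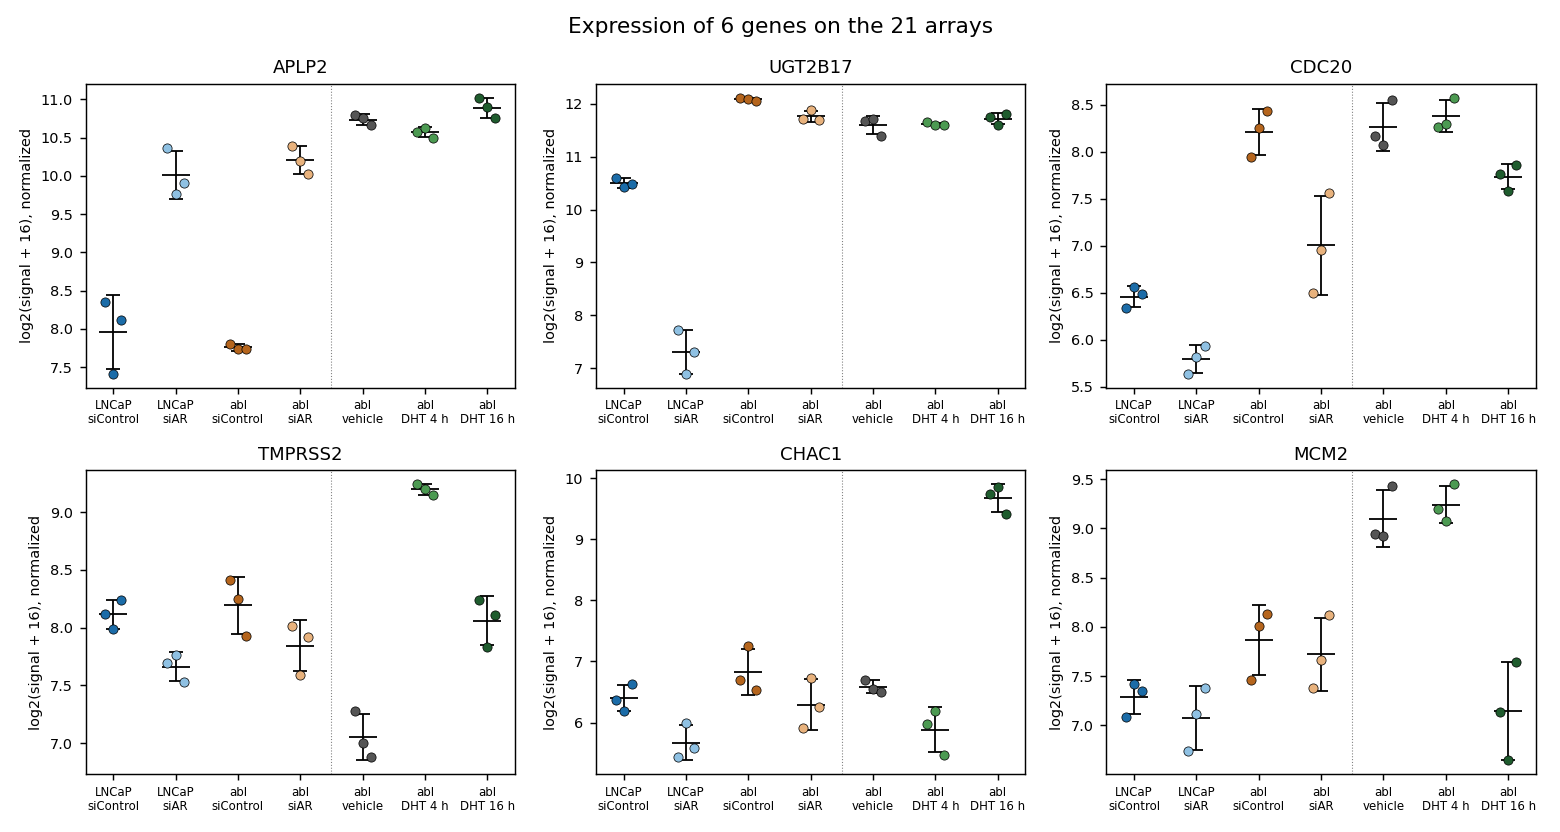
Normalized log2(signal + 16) of 6 genes on the 21 arrays, with 1 point per array, the group mean as a bar and the SD as whiskers (n = 3 per group); the dotted line separates the siRNA arrays from the DHT arrays. UGT2B17 fell under AR siRNA in LNCaP, with a smaller change in abl that did not pass, APLP2 rose in both, TMPRSS2 was highest after 4 h of DHT, and CHAC1 and MCM2 moved in opposite directions after 16 h.

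DHT was given to abl to ask whether the line still answers androgen, and how early. At 4 h the response was small: 5 genes changed, 4 of them known androgen-induced genes that were higher, and 1 lower (limma). An unadjusted p under 0.05 was found for 631 of 15611 genes. This is below the share of 0.05 that unchanged genes would give on average, so it shows no wider response. TMPRSS2, a transmembrane protease under AR control, rose from 7.05 ± 0.20 to 9.20 ± 0.05 (SD, n = 3), by log2 2.14 (SE 0.16, adjusted p = 5.05e-07). RHOU, an atypical Rho GTPase, rose by 1.49 (adjusted p = 4.79e-05), SLC45A3 by 1.38 (0.00335) and C1orf116 by 1.22 (0.000179). SERPINH1, a collagen chaperone, fell by 1.24 (0.00813).

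All 4 genes that rose belong to the androgen-induced list, of which 4 of 40 rose and 0 fell (13 and 0 when adjusted over the list alone). The list's median was log2 0.22 and its adjusted p 6.09e-20, and 1.26e-05 with an estimated correlation. FKBP5 was at 0.40 and KLK3 at 0.09 (adjusted p = 0.999 for each). The second KLK3 probe set was at 0.89 (SE 0.22, adjusted p = 0.371 over all probe sets), with signals of 2 to 7.3 under vehicle and 24 to 29 at 4 h. The mitosis list (median 0.09, 0 of 57 genes past the threshold; adjusted p = 0.0056, and 0.704 with an estimated correlation) and the ER folding list (median -0.13, 0 of 20; adjusted p = 0.0369, and 0.556 with an estimated correlation) were called with no single gene past the threshold, also when adjusted over each list alone. The mitosis list was at -0.14 after median centring, which moved the median of all genes to -0.16, and was not called without the third 4 h array (-0.01) or the first or second vehicle array (0.06 and 0.05). It was at 0.19 without the third vehicle array and 0.145 and 0.17 without the first or second 4 h array. The ER folding list was not called without the first or second vehicle array (-0.10 for each) or the first, the second or the third 4 h array (-0.13, -0.14 and -0.11). SERPINH1 lost its call without the first or second vehicle array (-1.20 and -1.22) or the first or the third 4 h array (-1.24 and -0.99). The share of higher genes was 80%, against 66.7% (4 against 2) with median centring and 100% (1 against 0) on the values as deposited.

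By 16 h of DHT the picture was a different one: 501 genes had changed, 249 higher and 252 lower, and 137 of them at least 2-fold (88 higher, 49 lower). Of the amino acid stress and ER folding genes, 21 of 24 and 8 of 20 rose, and of the DNA replication and mitosis genes, 24 of 51 and 10 of 57 fell. With an estimated correlation the mitosis list lost its call (adjusted p = 0.257) and the other 3 kept theirs. CHAC1, a glutathione-degrading enzyme of the stress response, rose the most, from 6.59 ± 0.10 to 9.67 ± 0.23 (SD, n = 3; log2 3.09, SE 0.23, adjusted p = 3.21e-07). MCM2, a subunit of the replicative helicase, fell the most (log2 -1.96, SE 0.25, adjusted p = 9.02e-05).

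The other genes with the largest rises were GDF15 (log2 2.95, SE 0.21), STYXL2 (2.44), S100P (2.44), the angiogenic factor VEGFA (2.39), the mitochondrial enzyme PCK2 (2.37), the stress transcription factor DDIT3 (2.34) and SESN2, a leucine sensor (2.11). S100P lost its call without the second 16 h array (1.91). Those with the largest falls were TUBA4A (-1.60, SE 0.19), CDC45 (-1.51), UHRF1 (-1.39), thymidylate synthase TYMS (-1.38), GINS2 (-1.38), the ribonucleotide reductase subunit RRM2 (-1.37) and the nucleoside transporter SLC29A1 (-1.36). TYMS lost its call without the first or second 16 h array (-1.25 and -1.27) or the third vehicle array (-1.24). On specific probe sets GDF15 (1.01) and GINS2 (-0.18) did not pass.

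Of 24 amino acid stress genes, 21 rose and 0 fell (24 and 0 when adjusted over the list alone). Their median change was log2 1.62, with an adjusted p of 6.81e-50, and 0.000419 with an estimated correlation. CHAC1, DDIT3, SESN2 and DDIT4, an inhibitor of mTOR signalling (2.10, SE 0.24), were the largest. Of 20 ER folding genes, 8 rose and 0 fell (12 and 0 when adjusted over the list alone), with a median of 0.48 and an adjusted p of 5.39e-17, and 0.0302 with an estimated correlation. They included ERN1, the ER stress sensor that splices XBP1 (1.80, SE 0.15), HERPUD1 (1.69), DNAJB9 (1.41) and SEL1L (1.37), the last 3 of ER protein folding and degradation.

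Of 51 DNA replication genes, 24 fell and 0 rose (39 and 0 when adjusted over the list alone). Their median was log2 -0.71, with an adjusted p of 4.28e-29, and 0.0302 with an estimated correlation. Of 57 mitosis genes, 10 fell and 0 rose (26 and 0 when adjusted over the list alone, which is not independent evidence), with a median of -0.55 and an adjusted p of 2.17e-16, and 0.257 with an estimated correlation. MAD2L1 (-1.25), ZWINT (-1.17), CCNA2 (-1.02) and TACC3 (-1.01) fell, and each lost its call without the second 16 h array (-1.15, -0.96, -0.94 and -0.88); MAD2L1 was at -0.55 on its specific probe set. Of 40 androgen-induced genes, 4 rose and 1 fell (10 and 2 when adjusted over the list alone; median 0.20, adjusted p = 4.35e-05, and 0.00934 with an estimated correlation; median 0.13 without the first 16 h array). TMPRSS2 rose by 1.01 (SE 0.16) and SLC45A3 by 0.98, and FKBP5 fell by 0.80 (SE 0.18, adjusted p = 0.0132). TSC22D3 rose by 1.90 on its brightest probe set and was at -0.22 on its specific one. SLC45A3 lost its call without the first 16 h array (0.85), and FKBP5 without the third vehicle array (-0.71) or the first or second 16 h array (-0.81 and -0.70). ESRP1, an epithelial splicing factor, was the 1 of 13 luminal genes that rose (1.56; 2 when adjusted over the list alone, and 0 fell; adjusted p = 0.00663, and 0.183 with an estimated correlation).

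The 16 h arrays were dimmer: the 2% trimmed mean signal was 48.7 ± 5.03 against 65.3 ± 2.66 on the vehicle arrays (SD, n = 3). The all-gene median shifted by log2 -0.31 at 16 h and -0.32 between 16 h and 4 h on the values as deposited, and by -0.16 at 4 h with median centring. The share of changed genes that were higher at 16 h was 49.7%, against 30.6% (167 against 379) with median centring and 20% (28 against 112) on the values as deposited. The count of 501 was 300, 292 and 241 without the first, the second or the third vehicle array, and 247 and 215 without the first or second 16 h array.

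**Figure D3:**
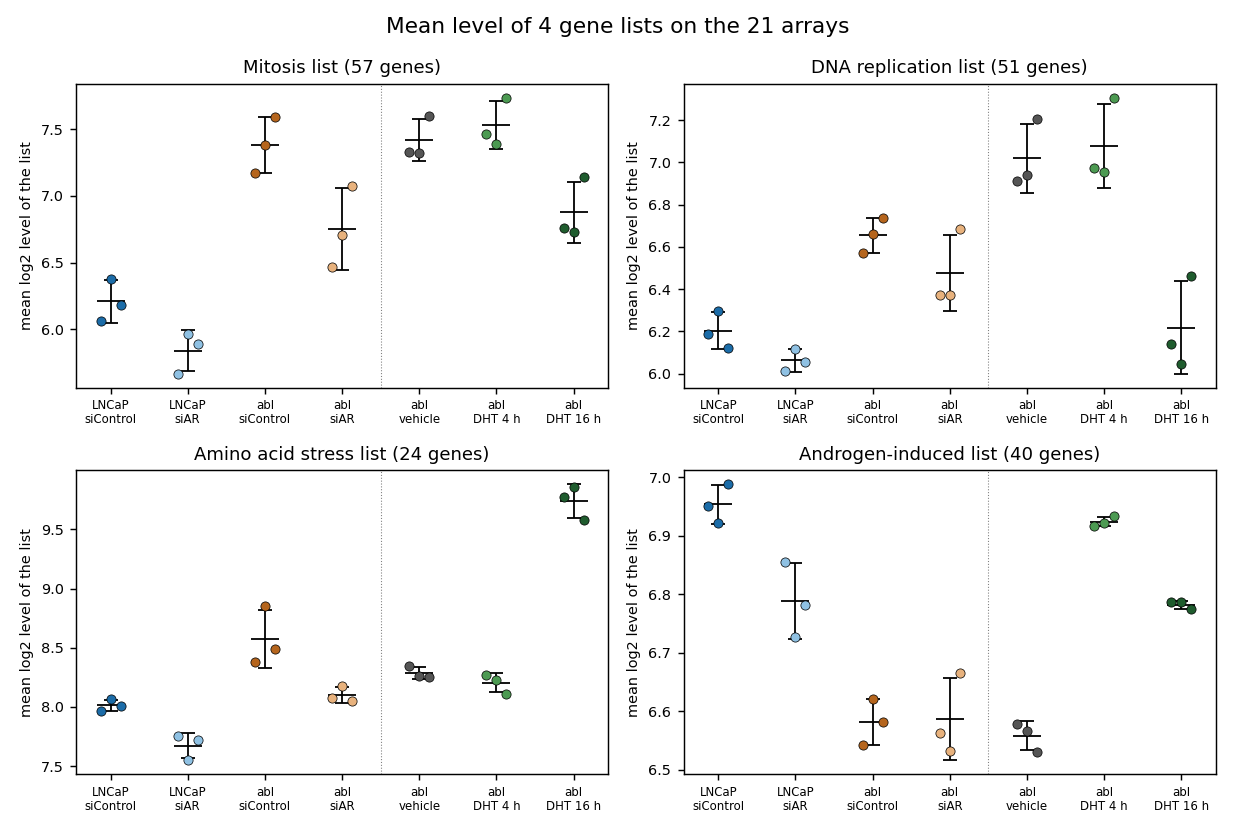
Mean log2(signal + 16) of the measured genes of 4 lists on each of the 21 arrays, with 1 point per array, the group mean as a bar and the SD as whiskers (n = 3 per group). The amino acid stress list was at 9.74 after 16 h of DHT and 8.29 under vehicle, DNA replication at 6.22 and 7.02, and the androgen-induced list was highest among the DHT arrays at 4 h (6.92).

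The time points were compared directly, and 774 genes differed between 16 h and 4 h, with 380 higher and 394 lower at 16 h. Among the androgen-induced genes, 7 of 40 were lower at 16 h than at 4 h: RHOU differed by log2 -1.47 (SE 0.15), FKBP5 by -1.20 (SE 0.18) and TMPRSS2 by -1.14 (SE 0.16, adjusted p = 0.000196). CHAC1 (3.79, SE 0.23), GDF15 (3.04), S100P (2.79), PCK2 (2.48), DDIT4 (2.27), VEGFA (2.23), PABPC1L (2.19) and STYXL2 (2.14) were the most raised. MCM2 (-2.10, SE 0.25), TUBA4A (-1.79), TYMS (-1.60), RRM2 (-1.57), CDC45 (-1.56), GINS1 (-1.51) and PCNA, the sliding clamp of DNA polymerase (-1.50), were the most lowered of those that held without any 1 array. NCAPH (-1.51) was at -1.07 without the second 16 h array, where its call was lost, and GDF15 was at 1.02 on its specific probe set, where its call was lost too.

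Of the lists, amino acid stress (22 of 24 genes higher, 0 lower; 24 and 0 when adjusted over the list alone, as in the brackets that follow), ER folding (11 of 20 and 0; 14 and 0) and DNA replication (0 of 51 and 28; 0 and 39) differed between the times with adjusted p of 1.92e-46, 8.02e-20 and 1.17e-28. With an estimated correlation those p were 0.000429, 0.0201 and 0.0302. The mitosis list (0 of 57 higher, 20 lower; 0 and 39) had an adjusted p of 6.09e-21, and 0.183 with an estimated correlation. The luminal list (2 of 13 higher, 0 lower; 4 and 1) and the p53 list (2 of 21 higher, GDF15 and GADD45A, 0 lower; 2 and 0) had adjusted p of 0.00109 and 0.0186, and 0.141 and 0.183 with an estimated correlation. The androgen-induced list was not called (7 of 40 lower, 1 higher, also when adjusted over the list alone; adjusted p = 0.0989). TMPRSS2 and SLC45A3 were the 2 genes that passed at both times, against 0.0638 for independent lists (Fisher's exact test, two-sided p = 0.00149, Benjamini-Hochberg 0.00596). Both times use the same vehicle arrays. The correlation of their fold changes across genes was 0.236, and the same sign was found for 58.1% of genes, while simulated unchanged groups gave 0.499 and 66.7%. The covariance was 0.0159, against 0.0246 simulated. The simulation used the spread estimated from all arrays, which may be larger than that of the DHT arrays, so it decides nothing about the covariance. Part of the overlap may come from the shared arrays. The share of genes higher at 16 h was 49.1%, against 75.5% (437 against 142) with median centring and 22.5% (36 against 124) on the values as deposited. The count of 774 was 427, 458 and 343 without the first, the second or the third 4 h array, and 338 and 299 without the first or second 16 h array.

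The last comparison asked whether genes that DHT raises in abl fall when AR is knocked down in the same line. At 16 h it found 37 genes that rose with DHT and fell with AR siRNA, against 4.48 for independent lists (Fisher's exact test, two-sided p = 1.83e-23, Benjamini-Hochberg 9.76e-23). Here too the Fisher p-values take genes as independent. As no vehicle array is stated to match 16 h, a change with DHT cannot be told apart here from one with time in culture. Chosen after their values were seen, examples are ASNS, ATF3, CEBPB, GDF15, MTHFD2, PCK2, PSAT1, S100P, SHMT2, TRIB3 and VEGFA, along with the aminoacyl-tRNA synthetase genes CARS1, GARS1, IARS1 and SARS1. On specific probe sets, after AR siRNA in abl, ATF3 was at 0.27 and GDF15 at -0.81, and GDF15 was at 1.01 at 16 h of DHT. None of these passed. A further 13 genes fell with DHT and rose with AR siRNA, against 5.80 (exact p = 0.0084, adjusted 0.0251), among them CCND1 (cyclin D1) and ACAT2, chosen in the same way. Genes that moved the same way numbered 8 higher and 7 lower, against 5.73 and 4.54 (exact p = 0.287 and 0.227, adjusted 0.51 and 0.454). None of the 5 genes changed by DHT at 4 h was changed by AR siRNA in abl, where 0.092 were expected at most in a pair of directions. The correlation across all genes was -0.0202 between 16 h of DHT and the knockdown, and -0.0858 at 4 h.

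The 65 genes shared by 16 h of DHT and the knockdown were 34 without the second control array or the second AR siRNA array of abl and 38 without the third control array of abl. They were 41, 36 and 39 without the first, the second or the third vehicle array and 38 and 32 without the first or second 16 h array. On the values as deposited, and also with the compared groups fitted alone, 0 genes were shared.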

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

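In this part the tests of scaling, time in culture, the control siRNA, array quality and the 3 exact tests of the mitosis list were chosen only after the result was seen.

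A difference between the lines in their response to AR siRNA, by limma's test of the interaction, picked out 6 genes: UGT2B17 (log2 2.87), LYSMD4 (2.38), ANGPT2 (1.91), UGT2B15 (1.17), PROS1 (1.13) and GCLC (-1.17). The same test on the lists picked out androgen-induced (median 0.23), mitosis (-0.29), cholesterol synthesis (0.34), NF-kB (-0.32) and luminal genes (0.30), with adjusted p of 0.00625, 5.11e-05, 0.000668, 0.00614 and 0.0319. With an estimated correlation these p were 0.05 (to 2 decimals), 0.576, 0.17, 0.145 and 0.314, so none of the 5 kept its call. Without 1 array the luminal list was not called at 0.08 (second AR siRNA array of LNCaP), 0.17 and 0.18 (the third and second of abl), 0.27 and 0.22 (first and second control arrays of LNCaP) and 0.23 (first of abl). The NF-kB list was not called at -0.19 (the third AR siRNA array of LNCaP), -0.24 (first of abl) and -0.34 and -0.35 (second and the third control arrays of abl). Mitosis was not called without the first AR siRNA array of abl (-0.17), nor the androgen-induced list without the third (0.16). No gene of these 5 lists passed the interaction by itself (0 of 40, 57, 19, 12 and 13 in limma; 1262 of all genes at an unadjusted p under 0.05); when adjusted over the list alone C1orf116, ACAT2, SC5D and CXCL8 did. Of 100 splits of the arrays within the lines, 17 gave at least 6 genes. The highest other split gave 1471; it swaps the labels in 1 line and so adds the 2 knockdowns up, and the next highest gave 358. Since such splits put the knockdowns themselves into the spread, they decide nothing about the 6 genes. ANGPT2, UGT2B15 and UGT2B17 kept their calls when each array was left out.

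A difference between 4 h and 16 h of DHT, tested directly, picked out 774 genes and 6 lists: amino acid stress (median log2 1.71), ER folding (0.58), DNA replication (-0.82), mitosis (-0.63), luminal (0.24) and p53 targets (0.14). With an estimated correlation the mitosis, luminal and p53 lists lost their calls (adjusted p = 0.183, 0.141 and 0.183), and without the second 4 h array the p53 median was 0.05. The highest of the other splits gave 1 gene, and 10 splits are too few for a share under 0.05. The same holds for the other comparisons, where 1 of 10 splits, the real one, gave as many genes: 499 and at most 23.2% of that for AR siRNA in LNCaP, 640 and 3 in abl, 3015 and 4 for abl against LNCaP, 5 and 1 at 4 h of DHT, and 501 and 1 at 16 h.

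The rise of the amino acid stress list at 16 h of DHT was weighed against brightness, scaling and time in culture. The 16 h arrays were dimmer, but the slope of the list on brightness within groups predicts a change of at most 0.0745 (upper 95% bound) against an observed 1.45 for the list mean. That slope was fitted to normalized values and rests mostly on the siRNA arrays, whose brightness varied most. The SD of the trimmed mean was 33.2 in LNCaP with AR siRNA, 2.66 under vehicle and 5.03 at 16 h. The bound therefore argues only against a trend of that kind. Under 4 scalings the list's median rose above that of all genes by 1.56 or more. A factor per array moves the list and all genes nearly alike, so this value could hardly differ between scalings. It shows that the list rose relative to all genes and does not weigh the scalings. The list was at -0.0773 at 4 h, and since no vehicle array is stated to match 16 h, a response to DHT cannot be told apart from one to time in culture, for example medium running short of amino acids, which may raise these genes and lower DNA replication.

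The 184 genes shared by the knockdowns were weighed as AR targets against 3 other readings. With the ACTB 3'/5' ratio as a covariate, 184 of 184 (100%) passed in both lines. The mean ratio under AR and control siRNA was 5.06 and 5.62 in LNCaP and 6.15 and 5.81 in abl. These differences lie within the SDs of 0.70 to 1.42. The covariate could thus remove few calls, and the result decides little about array quality. If AR drives the 184 genes, those that fell should rise with DHT more than those that rose. At 4 h the difference of medians was log2 0.16 (1000 random draws gave -0.05 to 0.05), while at 16 h it was -0.03 (-0.10 to 0.10), although 13 of the 61 genes that fell were called higher and 1 lower (3 and 4 of the 123 that rose), so an effect of the siRNA that does not run through AR stays possible for part of them. In abl the vehicle arrays were nearer to AR siRNA than to control siRNA for 59.8% of the genes, 72.1% of those that fell (random draws 41% to 67.2%) and 53.7% of those that rose (46.3% to 63.4%), against 53.6% of all tested genes. Vehicle minus control siRNA had a median of log2 -0.66 over genes that fell and 0.465 over genes that rose (-0.05 over all genes), where AR siRNA had -0.68 and 0.78. The same control siRNA arrays served to choose these genes, so part of this likeness is built in by the choice. The vehicle arrays also come from the other experiment, whose difference cannot be told apart from an effect of the control siRNA. Such an effect stays open for part of either set.

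The fall of the mitosis list after AR siRNA was weighed against brightness and a programme that varies from array to array; brightness predicts a change down to -0.0385 (lower 95% bound), against an observed -0.632 in abl. Over both lines the list mean changed by -0.501, with an exact permutation p of 0.005 (two-sided, treatment permuted within lines, 400 arrangements, the smallest they can give), which argues against array-to-array variation as the whole cause. Whether the fall was larger in abl than in LNCaP stays open: the difference was -0.262, and between arrays of one replicate number -0.305, -0.26 and -0.223, where the exact permutation p of 0.25 is the smallest that 8 arrangements can give. Permuting treatment within lines gave an exact p of 0.535, but puts the knockdown itself into the spread and decides nothing. A fall of dividing cells after loss of AR and a toxic effect of the siRNA both stay open, as neither was tested.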

How the results depend on the processing

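The settings chosen only after the data were seen were tests with scaling to a 2% trimmed mean, with the siRNA arrays numbered 1 left out or as a block, and with the ACTB 3'/5' covariate.

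Counts are given in the order abl against LNCaP (3015), AR siRNA in LNCaP (499) and in abl (640), the interaction (6), DHT at 4 h (5) and 16 h (501), 16 h against 4 h (774), then genes shared by the knockdowns (184), by 16 h of DHT and the knockdown in abl (65), and by both DHT times (2). Only counts that moved over 1.5 times are listed. On the values as deposited they were 985, 16, 6, 2, 1, 140, 160, 3, 0 and 0. With a fit of the compared groups alone they were 1649, 18, 1, 1, 2 (DHT at 4 h), 504 (16 h against 4 h), 1, 0 and 1. The spread is then estimated from fewer arrays, but the count for DHT at 16 h did not move over 1.5 times. Fewer arrays alone therefore need not account for the falls of the knockdown counts. In the main fit the siRNA comparisons share 1 estimate of the spread with the DHT arrays, so their calls depend on it. At an adjusted p of 0.01 they were 1830, 161, 188, 3, 231 (DHT at 16 h), 285, 68 and 19. Median centring gave 308 and 297 for the knockdowns, 3 for the interaction and 86 shared.

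A pseudocount of 64 gave 799 and 1005 for the knockdowns, 26, 11, 929, and 310, 167 and 4 shared; a pseudocount of 1 gave 12 for the interaction. Every probe set on its own gave 4813 probe sets for the lines, 13 for the interaction, 11 at 4 h and 4 shared by the DHT times. The mean of probe sets gave 10, 10 and 4 for those last 3. Trended and robust eBayes gave 16 for the interaction, 9 and 765 for DHT, and 123 and 4 shared. Array weights gave 404 in abl, 20, 1613 and 1600 for DHT, and 117 and 6 shared. The ACTB covariate gave 819, 1032, 16, 8 and 826, and 277 and 139 shared. The siRNA number 1 block gave 825, 1106, 14, and 328, 147 and 4 shared; without those 4 arrays 98 were shared by DHT and the knockdown. The cause of these moves was not tested.

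The replicate numbers do not pair the samples by the rule set before the data were examined. Deviations of siRNA arrays numbered 1 correlated at 0.22 to 0.33, of number 2 at 0.048 to 0.09 and of number 3 at 0.018 to 0.16, against -0.23 to 0.14 for different numbers; for DHT arrays they lay between 0.015 and 0.082, against -0.091 to 0.025. A fit with the replicate number as a block gave 979 genes in abl, 11 for the interaction, 763 at 16 h of DHT, and 296 and 149 shared.

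Leaving out each array in turn gave these ranges: 2511 to 2651, 166 to 478, 259 to 585, 3 to 14, 4 to 7, 215 to 519 and 299 to 709 genes, and 86 to 176, 32 to 80 and 1 to 2 shared. The probe set that stands for a gene was chosen anew each time, and the 2 arrays left in a group were assumed to vary like the other groups. Over 568 results, each a named gene in 1 comparison, 3541 of 3913 such values kept their direction and side of the threshold. Of the rest, 294 lost and 16 gained a call, 62 moved and 0 reversed. Over the other settings 8987 of 9655 did, 500 lost and 82 gained a call, 79 moved and 7 reversed. Those 7, the cause not tested, were ATF3 in abl (0.27), FAS (-0.15) and PTPRC (-0.0523) between the lines, TSC22D3 at 16 h (-0.22) and against 4 h (-0.17), all on specific probe sets, LUM in LNCaP with no filter (-0.31) and NR4A1 between the lines with the mean of probe sets (-0.02075).

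Of 42 called lists, 238 of 282 values without 1 array kept their call and 44 lost it; over other settings 692 of 768 kept it and 76 lost it, 32 of these with an estimated correlation. The mitosis list ran from -0.78 to -0.46 without 1 array in abl and from -0.42 to -0.17 for the interaction. Its call was lost with an estimated correlation in abl (-0.64, p = 0.183) and for the interaction (-0.29, p = 0.576), and there also in fry (-0.29, p = 0.406) and without the first AR siRNA array of abl (-0.17). The androgen-induced list kept its call at 4 h (0.20 to 0.25) and 16 h of DHT (0.13 to 0.22) without each array. Signal over background limits dim genes, whose changes the pseudocount shrinks.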

Other observations

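No test in this part was chosen only after the result was seen; the runs of genes below were looked up afterwards.

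Further genes of the fixed lists differed between the lines. The tight junction gene CLDN3 (log2 -2.36, SE 0.26) and the luminal keratins KRT18 (-0.90) and KRT8 (-0.83) were lower in abl, while the luminal list as a whole (1 of 13 higher, 4 lower; 2 and 5 when adjusted over the list alone) was not called (adjusted p = 0.118, and 0.441 with an estimated correlation). The interferon genes ISG15 (-1.86, SE 0.38) and IFI6 (-1.45) were lower, with 2 of 25 genes of their list higher and 3 lower and no call (adjusted p = 0.313). GDF15 was lower by the most among p53 targets (-3.10, but -0.44 on its specific probe set, where it did not pass), and the cystine importer SLC7A11 was higher (2.20, SE 0.24). In the androgen-repressed list (3 of 11 higher, 3 lower; adjusted p = 0.88), CAMK2N1 was lower (-2.83) and OPRK1, the kappa opioid receptor, higher (1.44). The ETS factor ETV1 was lower (-1.56) and the coactivator NCOA2 higher (0.79) among 12 AR cofactors, a list that was not called (1 higher, 1 lower; adjusted p = 0.478).

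At 16 h of DHT, 2 genes of the hypoxia and glycolysis list fell, LDHA (log2 -1.02, SE 0.16) and ENO1 (-0.50), while VEGFA rose (2.39, SE 0.19); the list was not called (1 of 19 higher, 2 lower; adjusted p = 0.313). ENO1 lost its call when any 1 array was left out (-0.45 without the third vehicle array). TUBB3, a neuronal tubulin, fell by 1.27 (SE 0.17). AMD1, of polyamine synthesis, was lower in abl than in LNCaP (-0.90, SE 0.13) and lower at 16 h than at 4 h of DHT (-0.68); its list was not called (1 of 8 higher, 1 lower between the lines; adjusted p = 0.842). The neuroendocrine list (2 of 13 higher, 2 lower; adjusted p = 0.939), the basal list (0 of 4 in limma, with none past the threshold when adjusted over the list alone; adjusted p = 0.645) and the leukocyte and endothelial list (1 of 9 higher, 1 lower; adjusted p = 0.656) were not called between the lines, and were not called in any other comparison.

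A hypothesis was tested that copy number differences set the lines apart, in which case neighbours on a chromosome should differ together. The difference between abl and LNCaP of a gene correlated at 0.186 with the median of its 20 nearest neighbours (15560 genes, where 20 shuffles of gene order gave -0.018 to 0.017). The highest value in another comparison was 0.0448, at 16 h of DHT (shuffles -0.02 to 0.016). AR siRNA gave 0.0364 in abl (shuffles -0.021 to 0.011) and 0.0199 in LNCaP (-0.012 to 0.021). Neighbours thus moved together weakly in some comparisons within 1 line too. Runs of 25 genes with the highest medians were PDE7A to LACTB2 (log2 0.60) and LMO4 to CCDC18-AS1 (0.56), and the lowest were DND1 to PCDHGA4 (-0.61) and LINC00668 to SPIRE1 (-0.60), where shuffled orders reached 0.44 and -0.45. This may reflect gains and losses of chromosome segments; shared regulation of neighbouring genes, as in the protocadherin cluster, was not tested apart from it, and DNA was not analysed here.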
